A study of Mus musculus with 12 samples.

How the data were processed

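Gene expression was measured in OP9 stromal cells on 12 Illumina BeadChip arrays, 3 each, by their labels, for vehicle at 0 h and for imatinib at 32, 64 and 96 h. The deposited non-normalized table gives, per the file headers, the signal intensity of each probe on each array on a linear scale with background still in it. Beside it the deposited table gives, per the file headers, a detection p-value per probe and array. The authors also deposited a table of intensity values normalized between arrays, and limma is the tool named in the submitters' processing notes. Its version, the steps, their settings, the scanner and the extraction software are not given in the sources used here. Log2 of those deposited values differed from the values computed here by at most 0.0193.

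The values used here were computed from the non-normalized table in R 4.3.3 with limma 3.58.1 and version 1.17.8 of the data.table package. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The neqc function corrected the background from the detection p-values, added an offset of 16, normalized all 12 arrays by quantiles and took log2. Of 45281 probes, 34885 list 1 gene symbol, 18 several and 10378 none. A probe was kept when its detection p was under 0.05 on at least 3 of the 12 arrays, which left 18897 probes, 15961 of them with 1 gene. A gene was represented by its kept probe with the highest mean log2 intensity, which gave 10211 genes, 3863 of them with more than 1 kept probe. Probes of 1 gene were called in opposite directions for Tmsb10 at 96 h and Rtraf at 64 h against vehicle. Symbols were checked against the RefSeq gene table of GRCm38.p6, used only for names; 627 of 628 list symbols matched.

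A linear model of 4 group means was fitted to all 12 arrays with limma (8 residual degrees of freedom), with moderated variances and Benjamini-Hochberg adjustment over the kept probes. A probe or gene that rose, fell or changed had adjusted p under 0.05. The 4 comparisons were 96 h against vehicle and 64 h against 32 h, each within 1 array label, and 32 h and 64 h against vehicle, each across 2 array labels. Values are log2 fold changes with the SE from the fit, and means with the SD over the 3 arrays. A fold against a group in which no array detected the gene is given as at least the fold against the lowest level detected on each array, or against the gene's own level where that was higher. Every p-value treats the arrays as independent samples.

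Gene lists were tested with camera in limma, with a preset correlation of 0.01 between genes, two-sided, over the 23 of 28 lists (21 pathway, 7 cell type) with at least 5 measured genes, adjusted over those lists. Of the calls, 0 at 96 h, 0 from 32 h to 64 h, 5 at 32 h and 1 at 64 h against vehicle held with a correlation estimated from the data. Genes named per comparison were the 10 largest increases and 10 largest decreases among called genes whose groups did not overlap. Added to them were up to 4 members of each list with the smallest p, all measured imatinib targets, and Il7, Cxcl12, Kitl, Vcam1 and Hes1; predicted and unnamed transcripts were left out. The groups, comparisons, tests, filter, thresholds, lists, naming rule and all alternatives but the 2 given next were chosen before the data were examined.

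The alternatives were no background correction, median scaling, each array label normalized on its own, only the 6 arrays compared, no filter, a strict filter (detection p under 0.01 on all 3 arrays of a group), offset 50, trended and robust variances, at least 1.5-fold change, the replicate number as a block, the deposited normalized values, an estimated correlation, the mean of a gene's probes, and each array left out in turn. Array weights and leaving out imatinib 32 h replicate 3 and 64 h replicate 3 together were added after the data had been seen. Median scaling took the background-corrected log2 values, centred on each array's median over the kept probes. No sample was left out of the main comparisons.

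The fit was tested on simulated data with 18897 probes, 50 of them changed at each fold. A 2-fold change was recovered for 76% of them at 96 h against vehicle, 64% from 32 h to 64 h, 76% at 32 h and 72% at 64 h against vehicle, and a 4-fold change for 100% in each. A 1.5-fold change was recovered for 24 to 32%, so a gene that did not pass can still differ by this much. The data called 13.3% of probes at 96 h and 11.7% at 64 h against vehicle, a larger share than was changed in the simulation. The adjustment is looser where more probes change, so the simulated recovery can be too low for these comparisons.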

Results

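OP9 cells, a mouse stromal line from newborn calvaria of mice with the op mutation of Csf1, were treated with vehicle or with imatinib, an inhibitor of the ABL, KIT and PDGF receptor tyrosine kinases. Biotin-labelled cRNA from total RNA was hybridised to Illumina BeadChips, 3 arrays per group, by their labels vehicle at 0 h and imatinib at 32, 64 and 96 h, 12 in all. The series is about resistance to imatinib that stromal cells give to BCR-ABL-positive lymphoblastic leukaemia cells, so genes of stromal support for lymphoid cells were among the lists tested. Each array read 45281 probes. The median signal ran from 104 to 112 intensity units, and 16162 to 17332 probes per array (35.7 to 38.3%) were detected. After normalization, arrays of 1 group correlated at r = 0.989 to 0.991, and their log2 values differed with an SD of 0.284 to 0.325. The number of arrays limits the precision: the median SE of a log2 fold change was 0.15. The p-values measure only the spread between these samples, since the labels do not say whether the 3 samples of a group were separate cultures.

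The 4 groups lay in order of their labelled times along the first principal component, which held 36.3% of the variance. Its scores were -31.9 to -31.2 for vehicle, -5.67 to -5.26 at 32 h, 13.4 to 14.8 at 64 h and 21.1 to 24.1 at 96 h. The labels give 2 array labels, 1 for the vehicle and 96 h samples and 1 for the 32 h and 64 h samples. The second component (10.5%) parted these: scores were 5.17 to 17.2 on array label 1 and -17.2 to -5.32 on array label 2. Array label 1 holds the first and last labelled times and array label 2 those between, so this component cannot tell array label from time. Comparisons within an array label are therefore given first.

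**Figure D1:**
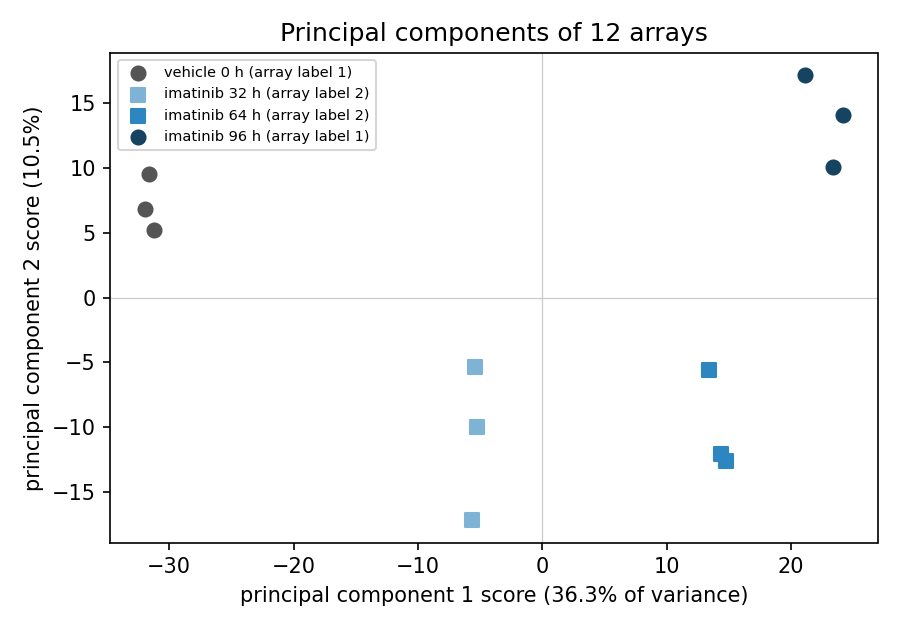
Scores of the 12 arrays on principal components 1 (horizontal, 36.3% of the variance) and 2 (vertical, 10.5%), 1 point per array. Circles are array label 1 and squares array label 2, and component 1 scores run from -31.9 in vehicle to 24.1 at 96 h.

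Imatinib at 96 h was compared with vehicle at 0 h to see what differed in the stromal cells after the longest exposure. Il7, the cytokine that early B cells need, rose 5.22-fold (log2 2.38 ± 0.12 SE, n = 3 per group). Cxcl12, the chemokine that holds haematopoietic cells in the marrow, rose 4.52-fold (2.18 ± 0.11). The largest increases were in Sort1, a sorting receptor (10.3-fold, 3.36 ± 0.14), and the adipokine Adipoq (8.23-fold, 3.04 ± 0.11). Rspo2, an activator of Wnt signalling, came next (2.89 ± 0.18). The Notch target Hey1 (2.64 ± 0.17), the integrin gene Itga1 (2.57 ± 0.16) and the growth factors Fgf10 (2.57 ± 0.11) and Vegfc (2.54 ± 0.13) were also among the 10 largest increases. Rgcc, Palmd and Slc24a3 lay between (2.71 to 2.89). Of the other probes of Sort1, 1 of 2 had the same sign, and Hey1 was detected on 2 and Vegfc on 1 of the 3 vehicle arrays.

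The largest decreases were in the proliferin genes Prl2c2 (25.1-fold lower, -4.65 ± 0.13), Prl2c3 (-4.58 ± 0.13) and Prl2c4 (-4.58 ± 0.12). These are close paralogs, so their probes cannot be assigned to single genes with certainty. Prl2c1 fell to a level not detected on any 96 h array, at least 7.4-fold lower. The water channel gene Aqp1 (-3.75 ± 0.13), the kinase gene Prkg2 (-3.57 ± 0.15, detected on 2 of 3 arrays at 96 h) and Timp3, an inhibitor of metalloproteinases (-3.20 ± 0.13), fell as well. Anxa8, Trem2 and Col18a1 completed the 10 (-2.99 to -2.51). The second probe of Col18a1 had the same sign but did not pass.

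**Figure D2:**
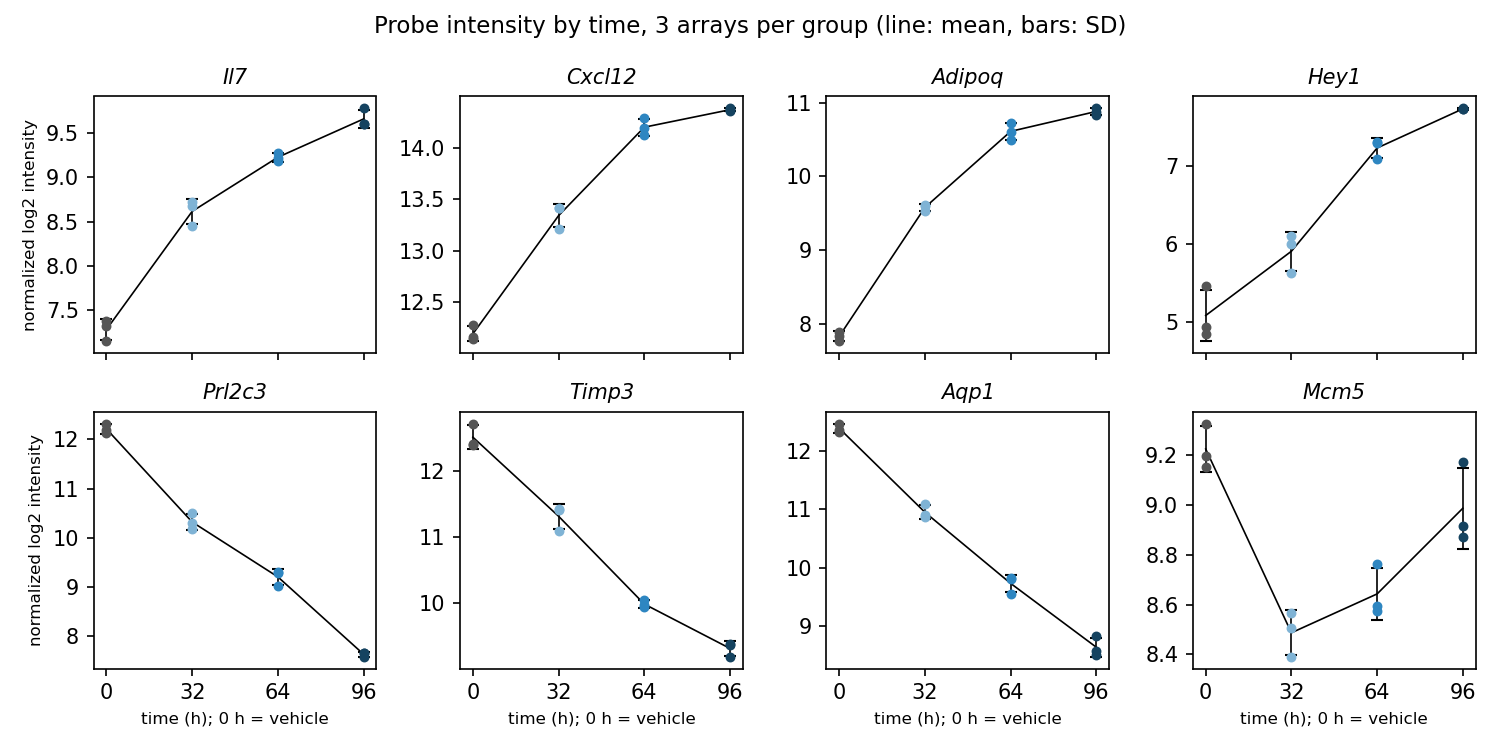
Normalized log2 intensity (vertical) of 8 genes by labelled time in hours (horizontal, 0 h is vehicle). Points are the 3 arrays of a group, lines join the group means and bars are the SD; Il7 (mean ± SD) was 7.28 ± 0.12 in vehicle and 9.66 ± 0.11 at 96 h, and Mcm5 9.22 ± 0.09 in vehicle and 8.49 ± 0.09 at 32 h.

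Haematopoietic niche factors rose as a group at 96 h: 8 of 23 measured genes rose and 2 fell (10 and 3 adjusted over the list alone), with a median log2 change of 0.28. The camera test gave adjusted p = 0.00185, and adjusted p = 0.217 with an estimated correlation. Beside Il7 and Cxcl12, Bmp4 (1.59 ± 0.12), the Notch ligand gene Jag1 (0.95 ± 0.15) and the vessel-stabilising factor gene Angpt1 (1.02 ± 0.13) rose. Kitl, which encodes stem cell factor, was at 0.45 ± 0.18 (adjusted p = 0.114) and Vcam1 at 0.01 ± 0.15 (adjusted p = 0.988). Of 9 Notch pathway genes, Hey1, Jag1 and Hes1 rose and none fell (4 and 0 adjusted over the list alone), with a median of 0.04 and adjusted p = 0.0676 for the list. Hes1 rose by 0.95 ± 0.22 and was detected on 2 of the 3 vehicle arrays.

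Genes that respond to receptor tyrosine kinases and ERK fell as a group: 9 of 23 fell and 2 rose (12 and 2 adjusted over the list alone), with a median of -0.33. The test gave adjusted p = 0.00145, and adjusted p = 0.217 with an estimated correlation. Among them were Hmga2 (-1.98 ± 0.17), the cyclin D1 gene Ccnd1 (-0.98 ± 0.12), the transcription factor gene Jun (-1.01 ± 0.12) and Spred1, an inhibitor of this pathway (-1.05 ± 0.13). Of 6 measured imatinib targets, Ddr1 rose (0.68 ± 0.18) and Nqo2 fell (-0.45 ± 0.12), 1 and 2 adjusted over the list alone. The list gave a median of -0.00487, a mean of 0.0268 and adjusted p = 0.901. Pdgfra (0.25 ± 0.16), Pdgfrb (0.29 ± 0.20), Csf1r (-0.26 ± 0.20) and Ddr2 (-0.35 ± 0.14) did not pass the test, and Abl1, Abl2 and Kit have probes that did not pass the detection filter. Without vehicle replicate 1 or 96 h replicate 3, Ddr1 no longer passed (adjusted p = 0.0792 to 0.0892). Nqo2 did not pass without vehicle replicate 2 or 3 or 96 h replicate 3 (adjusted p up to 0.0836).

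None of 22 G2/M and mitosis genes changed at 96 h (0 adjusted over the list alone; median 0.05, adjusted p = 0.901). Of 30 DNA replication genes, Cdt1, which licenses replication origins, fell (-0.74 ± 0.15), as did Rfc4 (-0.54 ± 0.16), and none rose (1 and 0 adjusted over the list alone; median -0.04, adjusted p = 0.432). Of 20 p53 targets and cyclin-dependent kinase inhibitors, the growth-arrest gene Gadd45a (1.55 ± 0.14) and Trp53inp1 rose and Mdm2 fell, the same 2 and 1 adjusted over the list alone. That list's median was -0.00548 while its mean and its test pointed up (adjusted p = 0.901).

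Genes of the contractile cytoskeleton and YAP/SRF targets rose as a group: 8 of 19 rose and 2 fell (9 and 2 adjusted over the list alone), with a median of 0.41. The test gave adjusted p = 0.00185, and adjusted p = 0.135 with an estimated correlation. The smooth muscle genes Actg2 (1.68 ± 0.13), Myl9 (1.17 ± 0.13) and Tagln (1.09 ± 0.13) and the tropomyosin gene Tpm1 (0.98 ± 0.11) rose, and the receptor kinase gene Axl fell (-1.11 ± 0.11). Matrix genes changed in both directions, 9 of 29 up and 6 down (10 and 6 adjusted over the list alone). Timp1 (-1.99 ± 0.12), Fbln2 (-1.55 ± 0.12) and fibronectin, Fn1 (-1.04 ± 0.12), fell, and Thbs1, which encodes thrombospondin 1 (2.04 ± 0.16), and the crosslinking enzyme gene Lox (0.87 ± 0.12) rose. The matrix list's median was 0.15, its mean -0.09 and its test pointed up (adjusted p = 0.787). Of 18 integrin and focal adhesion genes, 4 rose and 4 fell (4 and 5 adjusted over the list alone; median 0.05, adjusted p = 0.865). Itgb1 rose (0.94 ± 0.20), Itga2 rose at least 1.3-fold from an undetected level, and Itga5 (-1.14 ± 0.12) and Itga3 (-1.10 ± 0.18) fell.

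Among 18 adipocyte genes 6 rose and 1 fell (6 and 2 adjusted over the list alone; median 0.10, adjusted p = 0.062). Beside Adipoq, the lipase gene Lpl (1.42 ± 0.12) and Dgat1, an enzyme of triglyceride synthesis (0.93 ± 0.14), rose, and the fatty acid transporter gene Cd36 rose at least 2.37-fold from a level detected on no vehicle array. Of 9 osteoblast genes, Tnfrsf11b, the osteoclast inhibitor osteoprotegerin (1.64 ± 0.15), Omd (1.37 ± 0.16) and the transcription factor gene Sp7 (1.11 ± 0.12) rose and Bglap2 fell (-0.49 ± 0.14). The same 3 and 1 passed adjusted over the list alone. The osteoblast list had a median of -0.11, a mean of 0.28 and a test pointing up (adjusted p = 0.451). Of 5 chondrocyte genes, the transcription factor gene Sox5 (-1.37 ± 0.12) and the cartilage collagen gene Col2a1 (-0.94 ± 0.11) fell and Comp rose (0.43 ± 0.13). The counts were the same adjusted over the list alone (median -0.19, adjusted p = 0.0928).

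Stress and metabolic lists did not pass the test at 96 h. Of 19 NRF2 targets 1 rose and 4 fell (1 and 5 adjusted over the list alone; median -0.15, adjusted p = 0.0815). Nqo1 fell (-1.48 ± 0.13) and Gclm rose (0.71 ± 0.15). Of 20 hypoxia and glycolysis genes Adm rose and Pkm (-0.96 ± 0.11), Aldoa and Pgk1 fell (the same 1 and 3 adjusted over the list alone; median -0.18, adjusted p = 0.0676). Of 18 cholesterol synthesis genes Sqle (0.75 ± 0.12) and Ebp rose and none fell (5 and 1 adjusted over the list alone; median 0.19, adjusted p = 0.0815). Of 26 unfolded protein response and ATF4 genes 2 rose and 4 fell, the same adjusted over the list alone (median -0.06, adjusted p = 0.451). Trib3 (-0.96 ± 0.21) and Chac1 (-0.73 ± 0.12) fell and Dnajc3 rose (0.70 ± 0.12). Of 14 heat shock genes Hspa1b rose (1.28 ± 0.14) and Bag3 fell (-0.93 ± 0.11), 5 and 2 adjusted over the list alone (median 0.09, adjusted p = 0.787). Lamp2 and Ctsk rose and Sqstm1 fell among 31 lysosome and autophagy genes, 0 and 0 adjusted over the list alone (median 0.09, adjusted p = 0.568).

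Of 19 interferon response genes, Bst2 (at least 1.8-fold) and Tap1 (at least 1.44-fold) rose from undetected levels, Ifit3 fell (-1.17 ± 0.31) and Ccl5 fell at least 1.28-fold to an undetected level. The counts were the same adjusted over the list alone (median -0.17, adjusted p = 0.447). Of 18 inflammatory and NF-kB targets Mmp13 rose (1.11 ± 0.20) and Ccl9 (-0.86 ± 0.14), Nfkbiz (-0.77 ± 0.18) and Relb fell, 2 and 3 adjusted over the list alone. The median was 0.01, the mean -0.01 and the test pointed down (adjusted p = 0.901). Among 13 mesenchymal stromal cell markers Itgb1 and Alcam (0.68 ± 0.14) rose and Cd44 (-1.35 ± 0.11), Vim (-0.87 ± 0.12) and Eng (-0.66 ± 0.19) fell, the same 2 and 3 adjusted over the list alone (median -0.29, adjusted p = 0.365). Of 5 measured myeloid markers Lyz2, which has the close paralog Lyz1, rose (1.93 ± 0.15) and Cd14 fell (-0.96 ± 0.21, detected on 2 of 3 arrays at 96 h), the same adjusted over the list alone (median 0.01, adjusted p = 0.692). Most markers of other cell types with a probe did not pass the detection filter: 1 of 11 B lymphoid genes with a probe (Ms4a1, -0.15 ± 0.19), 2 of 12 endothelial, 2 of 9 muscle, 3 of 10 epithelial and 2 of 6 erythroid genes did. The lists hold 3 more B lymphoid, 2 muscle and 3 erythroid genes with no probe. Of these, Acta1, a muscle actin gene detected on 1 of 3 vehicle arrays, rose (1.27 ± 0.26) and no other passed. Adjusted over the list alone, 1 epithelial gene (Cldn7) and 1 erythroid gene (Klf1) were also higher, both detected on no vehicle array.

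Members that complete the smaller counts at 96 h, some chosen after their values were seen, were Tslp and Wnt5a (lower) among niche factors and Fos and Phlda1 (higher) among tyrosine kinase and ERK response genes. Tpm2 fell among contractile genes, Vcl rose and Itgb5 and Pxn fell beside Itga1 and the integrins given, and Cebpb fell among adipocyte genes. Srxn1, Osgin1 and Gclc fell among NRF2 targets, and Ddit3 and Psat1 fell and Dnajb9 rose among unfolded protein response genes.

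At 96 h against vehicle, 1238 probes (767 genes) rose and 1279 (753 genes) fell of 18897 tested (limma, adjusted p under 0.05), and 170 and 166 of these genes changed at least 2-fold. In 33.3% of genes the groups did not overlap, against 10% by chance. The sample labels put vehicle at 0 h, while the series design text can be read as vehicle for 32, 64 and 96 h, so the time of the vehicle samples is in doubt. If it was 0 h, drug and culture time are not separated in any comparison with vehicle. Among the genes named for this comparison, Relb, Tap1, Lamp2, Mdm2, Sqstm1, Trp53inp1, Ebp, Ctsk, Comp, Rfc4, Ifit3, Adm, Bst2, Pgk1, Aldoa, Bglap2 and Ddit3 each lost the call without at least 1 array, with adjusted p up to 0.176 over the alternatives that ended a call. Second probes of Itgb1, Comp and Pkm had the opposite sign to those given. So had 1 of 2 other probes of Mdm2 and 2 of 4 of Lamp2. Second probes of Itga5, Ddr1, Ifit3, Sqle, Rfc4 and Ddit3 had the same sign but did not pass.

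Imatinib at 64 h was compared with 32 h, within array label 2, for the change under continued exposure. The labels give no vehicle sample at 32 h or 64 h, so drug and culture time are not separated here either. Hey1 rose 2.5-fold (1.32 ± 0.17), Vegfc 2.33-fold (1.22 ± 0.13) and Fgf10 2.23-fold (1.16 ± 0.11) between these times. The monooxygenase gene Fmo1 had the largest increase (2.83-fold, detected on 2 of 3 arrays at 32 h), and Rspo2 (1.15 ± 0.18), Itga1 (1.09 ± 0.16) and Adipoq (1.03 ± 0.11) rose. The kallikrein gene Klk8 (-1.42 ± 0.13, detected on 1 of 3 arrays at 64 h), Timp3 (-1.33 ± 0.13), Aqp1 (-1.22 ± 0.13), Col18a1 (-1.17 ± 0.14) and Prl2c3 (-1.12 ± 0.13) fell most. The remaining 4 of the 10 largest increases were Epha7, Rasl11a, Rbp4 and Lyz2 (1.04 to 1.19), and of the decreases Adssl1, Trem2, Tmem184a, Aldh3a1 and Prl2c2 (-1.08 to -0.96). Epha7 and Tmem184a each have a second probe with the opposite sign. With the pair of arrays that stood apart left out, Rspo2 (adjusted p = 0.121), Rasl11a (0.0828), Itga1 (0.0623), Lyz2 (0.059) and Rbp4 (0.0529) did not pass. Their log2 changes were then 0.98, 1.15, 1.05, 1.01 and 1.16, with fewer arrays per group.

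Niche factors rose as a group from 32 h to 64 h. Cxcl12 (0.86 ± 0.11) and Il7 (0.61 ± 0.12) passed and none of the 23 fell (5 and 1 adjusted over the list alone; median 0.15, adjusted p = 0.0104, and adjusted p = 0.331 with an estimated correlation). Hypoxia and glycolysis genes fell as a group, with no single gene of 20 past the test (0 higher and 1 lower adjusted over the list alone; median -0.13, adjusted p = 0.0104, and adjusted p = 0.331 with an estimated correlation). Both group calls ended without 32 h replicate 2 (adjusted p = 0.0809 for niche factors and 0.0526 for hypoxia) and without 64 h replicate 2 (0.169 and 0.107). The Il7 call ended without 32 h replicate 1 or 2 or without any of the 3 arrays at 64 h (adjusted p = 0.0583 to 0.129 over 7 of 25 alternatives). DNA replication genes had a median of 0.0707 (adjusted p = 0.611).

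From 32 h to 64 h, 99 probes (67 genes) rose and 92 (59 genes) fell, 12 and 8 of these genes at least 2-fold, and 17.1% of genes had groups that did not overlap against 10% by chance. Leaving out 1 array took the rising probes to 49 (32 h replicate 1), 62 (32 h replicate 3) or 60 (64 h replicate 1, 2 or 3), and the falling probes to 52, 61 and 53 (32 h replicates 1, 2 and 3) or 51 and 55 (64 h replicates 2 and 3). With these 6 arrays alone, 60 rose and 59 fell. Leaving out 32 h replicate 3 and 64 h replicate 3 together gave 20 and 23. These arrays stood apart on the third component, at opposite ends (scores -20.35 and 20.19). Leaving them out also leaves fewer arrays per group, so the lower counts cannot be put down to these arrays alone.

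The changes at 96 h against vehicle and from 32 h to 64 h share no array. In both, 114 genes changed the same way: 62 rose and 52 fell, against 5.03 and 4.35 from the product of the shares. Both comparisons come from the same fit, on arrays normalized together, and share each gene's estimate of the spread. The product of the shares does not allow for this. By the labels both also run from an earlier to a later time, so drug and culture time are not separated in either. No gene changed in opposite directions, and 124 of the 126 genes that changed from 32 h to 64 h had the same sign at 96 h. Il7, Cxcl12, Adipoq, Hey1 and Fgf10 rose in both, and Timp3, Aqp1, Col18a1 and Trem2 fell in both. Across 10211 genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.552 and Spearman rho = 0.41. The count of 114 was 68 and 72 without 32 h replicates 1 and 3, 75, 70 and 71 without 64 h replicates 1, 2 and 3, and 29 without the pair of arrays that stood apart.

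**Figure D3:**
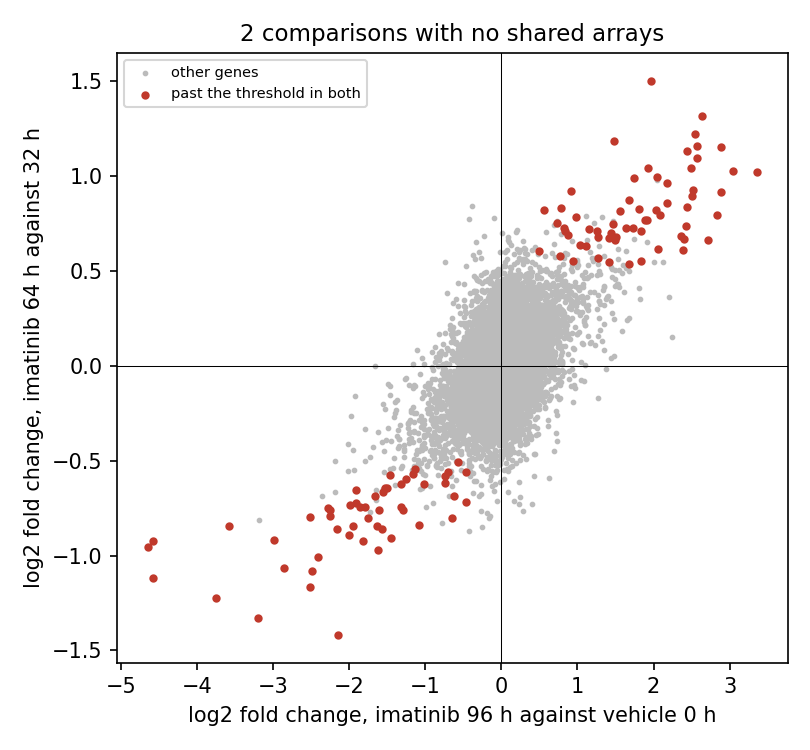
Log2 fold change of each of 10211 genes at 96 h against vehicle (horizontal) and at 64 h against 32 h (vertical). Red points are the 114 genes past the threshold in both, all with the same sign in both comparisons.

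Imatinib at 32 h was compared with vehicle for the earliest changes. Il7 rose 2.53-fold (1.34 ± 0.12), Cxcl12 2.22-fold (1.15 ± 0.11) and Adipoq 3.35-fold (1.74 ± 0.11). The exchanger gene Slc24a3 had the largest increase (1.94 ± 0.14). Rgcc (1.70 ± 0.13), the amine oxidase gene Aoc3 (1.51 ± 0.13), Cdo1 (1.46 ± 0.14) and Sort1 (1.37 ± 0.14) came next, and Palmd, Ogn and Slc1a3 rose by 1.32 to 1.33. Prl2c4 (-2.16 ± 0.12), Prl2c2 (-1.99 ± 0.13), Prl2c3 (-1.89 ± 0.13), Prl2c1 (-1.88 ± 0.22), Prkg2 (-1.88 ± 0.15) and Aqp1 (-1.43 ± 0.13) had the largest decreases. Rbfox1, Evi2a, Tafa5 and Arhgap22 were at -1.42 to -1.33.

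Genes of cell division were lower at 32 h. Of 30 DNA replication genes 9 fell and none rose (14 and 0 adjusted over the list alone; median -0.37, adjusted p = 1.61e-11, 0.00156 with an estimated correlation). Among them were Cdt1 (-1.07 ± 0.15), the helicase gene Mcm5 (-0.74 ± 0.12) and Mcm10 (-0.74 ± 0.14). Of 22 G2/M and mitosis genes 6 fell and none rose (15 and 0 adjusted over the list alone; median -0.42, adjusted p = 1.49e-10, 0.00505 with an estimated correlation). Prc1, needed for cytokinesis, was among them (-0.60 ± 0.12). Tyrosine kinase and ERK response genes fell as a group, 7 of 23 down and 1 up (11 and 1 adjusted over the list alone; median -0.38, adjusted p = 3.91e-07, 0.044 with an estimated correlation). Among them were Hmga2 (-1.25 ± 0.17) and Spred1 (-0.66 ± 0.13). Of 5 chondrocyte genes Sox5 (-0.92 ± 0.12) and Col2a1 (-0.77 ± 0.11) fell and Comp rose (0.80 ± 0.13), the same adjusted over the list alone. The chondrocyte list's median was -0.31 with adjusted p = 0.0235, and adjusted p = 0.0892 with an estimated correlation. The call ended without vehicle replicate 3 (0.079) or 32 h replicate 1 (0.0505).

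Contractile and YAP/SRF genes rose at 32 h, 5 of 19 up and none down (5 and 1 adjusted over the list alone; median 0.30, adjusted p = 2.71e-05, 0.0128 with an estimated correlation). Among them were Tagln (0.97 ± 0.13), Actg2 (0.96 ± 0.13) and Myl9 (0.83 ± 0.13). Cholesterol synthesis genes rose, 4 of 18 up and none down (5 and 0 adjusted over the list alone; median 0.19, adjusted p = 0.000313, 0.044 with an estimated correlation). These included Sqle (0.62 ± 0.12) and, less surely, Hsd17b7 (0.50 ± 0.11) and the lipid transfer gene Stard4 (0.55 ± 0.14). Niche factors rose, 5 of 23 up and 1 down (7 and 1 adjusted over the list alone; median 0.21, adjusted p = 0.000807, and adjusted p = 0.0853 with an estimated correlation). Of these, Jag1 was at 0.77 ± 0.15. Adipocyte genes rose, 4 of 18 up and none down (5 and 0 adjusted over the list alone; median 0.19, adjusted p = 0.00605, and adjusted p = 0.109 with an estimated correlation). Of these, Lpl was at 0.74 ± 0.12 and Cd36 was at least 1.44-fold higher.

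Members that complete the smaller counts at 32 h, some chosen after their values were seen, were Tpm1 and Vcl (contractile), Insig1 (cholesterol synthesis), Angpt1 and Bmp4 (niche) and Adipoq and Dgat1 (adipocyte), all higher. Spry4 rose among tyrosine kinase and ERK response genes and Tslp fell among niche factors. Of 2 muscle markers, Acta1 rose (1.27 ± 0.26, detected on 1 of 3 vehicle arrays), a call lost in 3 of 25 alternatives (adjusted p up to 0.0568). Of 13 mesenchymal stromal cell markers 1 rose and 2 fell (2 and 4 adjusted over the list alone; median -0.0738, adjusted p = 0.471), and no B lymphoid, myeloid, endothelial, epithelial or erythroid marker passed. Of 25 alternatives, Stard4 lost its call in 17 (adjusted p up to 0.177), Hsd17b7 in 7 (0.0758), Insig1 in 7 (0.126), Vcl in 6 (0.101), Angpt1 in 5 (0.0834), Dgat1 in 3 (0.0746), and Sqle (0.0604), Jag1 (0.0559) and Cd36 (0.0538) in 1 each. Hsd17b7 lost it without any 1 of the 6 arrays compared. Of the other probes of Insig1 and of Sort1, 1 of 2 had the same sign.

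At 32 h, 345 probes (213 genes) rose and 357 (212 genes) fell against vehicle, 33 and 30 of the genes at least 2-fold, and groups did not overlap in 23.1% of genes against 10% by chance. The groups carry different array labels, so array label and group cannot be told apart here, and with each array label normalized on its own 289 probes rose and 494 fell. Without vehicle replicate 2 or 3 or 32 h replicate 2 or 3, 212, 214, 227 and 209 probes rose. Without vehicle replicates 1, 2 or 3 or 32 h replicates 1, 2 or 3, 202, 188, 209, 231, 225 and 201 fell.

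Imatinib at 64 h was compared with vehicle in the same way. Il7 rose 3.87-fold (1.95 ± 0.12), Cxcl12 4.03-fold (2.01 ± 0.11) and Adipoq, the largest increase, 6.83-fold (2.77 ± 0.11). Rgcc (2.62 ± 0.13), Slc24a3 (2.60 ± 0.14), Fgf10 (2.43 ± 0.11), Sort1 (2.39 ± 0.14) and Rspo2 (2.27 ± 0.18) followed. Adamts9, Aoc3, the growth factor receptor gene Fgfr2 and Hey1 rose by 2.14 to 2.23, and a second probe of Adamts9 had the opposite sign. Prl2c4 (-3.08 ± 0.12), Prl2c3 (-3.01 ± 0.13), Prl2c2 (-2.95 ± 0.13), Prkg2 (-2.72 ± 0.15), Prl2c1 (-2.69 ± 0.22), Aqp1 (-2.66 ± 0.13) and Timp3 (-2.53 ± 0.13) fell most. Anxa8, Klk8 and Tafa5 were at -2.20 to -2.16.

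At 64 h DNA replication genes were lower, 8 of 30 down and none up (14 and 0 adjusted over the list alone; median -0.33, adjusted p = 3.96e-06, 0.0136 with an estimated correlation). Among them were Cdt1 (-1.11 ± 0.15) and Mcm5 (-0.58 ± 0.12). G2/M and mitosis genes fell as a group, 4 of 22 down and none up (10 and 0 adjusted over the list alone; median -0.35, adjusted p = 7.83e-05, and adjusted p = 0.0664 with an estimated correlation). Of these, Birc5, which encodes survivin, was at -0.66 ± 0.12. Tyrosine kinase and ERK response genes fell, 10 of 23 down and none up (12 and 2 adjusted over the list alone; median -0.43, adjusted p = 2.34e-05, and adjusted p = 0.0711 with an estimated correlation). Of these, Hmga2 was at -1.52 ± 0.17 and Ccnd1 at -1.05 ± 0.12. Hypoxia and glycolysis genes fell, 6 of 20 down and none up, the same adjusted over the list alone (median -0.15, adjusted p = 0.0226, and adjusted p = 0.21 with an estimated correlation). Of these, Pkm was at -0.54 ± 0.11, and the call ended without 64 h replicate 2 (0.0654) and with the mean of each gene's probes (0.0988).

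Niche factors rose at 64 h, 10 of 23 up and 1 down, the same adjusted over the list alone (median 0.16, adjusted p = 0.00065, and adjusted p = 0.0711 with an estimated correlation). Among them were Jag1 (1.10 ± 0.15) and Bmp4 (1.04 ± 0.12). Cholesterol synthesis genes rose, 5 of 18 up and none down (7 and 0 adjusted over the list alone; median 0.28, adjusted p = 0.000742, and adjusted p = 0.0711 with an estimated correlation). Of these, Sqle was at 0.85 ± 0.12. Contractile and YAP/SRF genes rose, 6 of 19 up and 1 down (7 and 1 adjusted over the list alone; median 0.26, adjusted p = 0.00611, and adjusted p = 0.0711 with an estimated correlation). Of these, Actg2 was at 1.22 ± 0.13. Adipocyte genes rose, 5 of 18 up and 1 down (6 and 1 adjusted over the list alone; median 0.05, adjusted p = 0.0468, and adjusted p = 0.21 with an estimated correlation). Of these, Lpl was at 1.41 ± 0.12 and Cd36 was at least 2.09-fold higher. Notch pathway genes rose, with Hey1 and Jag1 up and none of 9 down (3 and 0 adjusted over the list alone; median 0.17, adjusted p = 0.0493, and adjusted p = 0.135 with an estimated correlation). The adipocyte call ended without vehicle replicate 3, 96 h replicate 1 or 64 h replicate 1 or 3 (adjusted p = 0.0536 to 0.069), without background correction (0.0624), with median scaling (0.0504), with no filter on dim probes (0.0868) and with the pair of arrays that stood apart left out (0.0736). The Notch call ended without vehicle replicate 1 or 3, 96 h replicate 1 or 3, 32 h replicate 1 or 2 or 64 h replicate 2 (0.0566 to 0.123). It also ended with the replicate number as a block (0.0535), with array weights (0.0599) and with no filter on dim probes (0.105).

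Members that complete the smaller counts at 64 h, some chosen after their values were seen, were Top2a, Bub1b and Cenpa (G2/M, lower) and Dhcr7, Insig1, Hsd17b7 and Stard4 (cholesterol synthesis, higher). Adipoq, Dgat1 and Scd2 rose and Cebpb fell among adipocyte genes, Axl fell among contractile genes and Tslp among niche factors. Among markers of other cell types, Acta1 (muscle, 1.10 ± 0.26, detected on 1 of 3 vehicle arrays) and Lyz2 (myeloid, 1.47 ± 0.15) rose and no other passed. Of 13 mesenchymal stromal cell markers 1 rose and 4 fell, the same adjusted over the list alone (median -0.24, adjusted p = 0.129). Of 25 alternatives, Hsd17b7 lost its call in 8 (adjusted p up to 0.0859), Cenpa in 6 (0.106), Top2a in 4 (0.0703), Bub1b in 3 (0.0754) and Insig1 in 3 (0.0803). A second probe of Pkm had the opposite sign, as had 1 of 2 other probes of Insig1 and of Sort1.

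At 64 h, 1077 probes (646 genes) rose and 1128 (621 genes) fell against vehicle, 132 and 93 of the genes at least 2-fold, and groups did not overlap in 32.3% of genes against 10% by chance. The groups again carry different array labels, which cannot be told apart from the treatment, and with each array label normalized on its own 889 probes rose and 1414 fell.

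**Figure D4:**
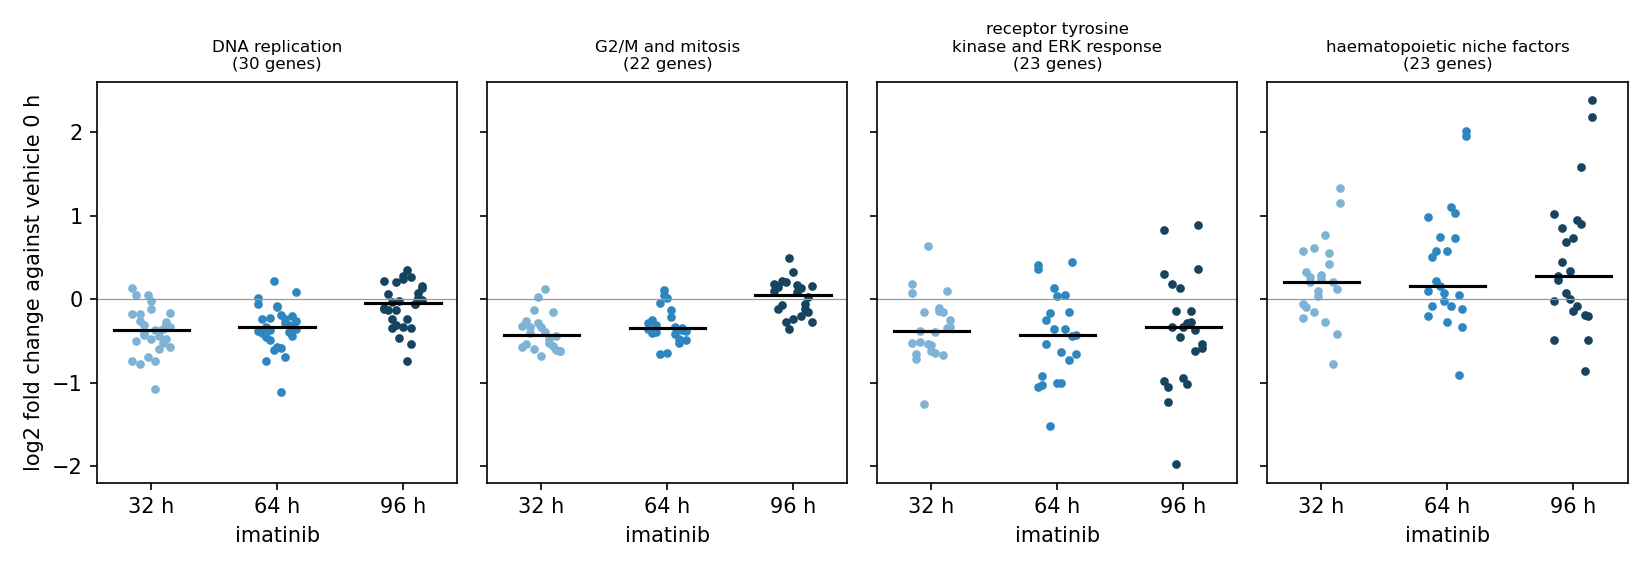
Log2 fold change against vehicle (vertical) at 32, 64 and 96 h of imatinib (horizontal) for 4 gene lists, with a point per gene and a bar at the median. The DNA replication median was -0.37 at 32 h, -0.33 at 64 h and -0.04 at 96 h, and the niche factor median 0.21, 0.16 and 0.28.

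Against vehicle, 336 genes changed the same way at all 3 times, 181 up and 155 down, against 1.01 and 0.951 from the product of the shares. The count was 0 in 100 simulations in which no gene changed. Almost no gene passes the adjustment in that setting, so the simulations cannot show how much overlap the shared controls give. Il7, Cxcl12, Adipoq, Jag1, Bmp4 and Lpl rose at every time, and Prl2c2, Prl2c3, Aqp1, Timp3, Hmga2 and Sox5 fell at every time. Of 425 genes changed at 32 h, 345 changed the same way at 96 h, as did 955 of the 1267 genes changed at 64 h, and none passed in the opposite direction. The 3 comparisons share the vehicle arrays, and 3 arrays cannot be split into 2 sets of 2, so part of the excess can come from those controls. The count of 336 was 216 without vehicle replicate 2, 217 without 32 h replicate 3 and 213 without the pair of arrays that stood apart.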

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

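The tests of brightness, normalization and shared batch on the cell division lists, of the proliferin probes and of mature adipocytes were chosen after the result was seen, and so were the comparisons of 96 h with 32 h and with 64 h; the splits of the arrays were planned. The comparison of 64 h with 32 h is the test of whether the effect against vehicle differs between these times. It does not separate drug from culture time, since the labels give no vehicle sample at either.

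From 32 h to 64 h, 99 probes rose and 92 fell, niche factors rose (adjusted p = 0.0104) and hypoxia and glycolysis genes fell (adjusted p = 0.0104). With an estimated correlation both lists were at adjusted p = 0.331, and both calls ended without 32 h replicate 2 (0.0809 and 0.0526) or 64 h replicate 2 (0.169 and 0.107). The genes with the largest rise were Fmo1 (1.5 log2), Hey1 (1.32), Vegfc (1.22), Epha7 (1.19), Fgf10 (1.16), Rspo2 (1.15), Rasl11a (1.14), Itga1 (1.09), Rbp4 (1.04), Lyz2 (1.04) and Adipoq (1.03). Smaller rises were in Thbs1 (0.99), Cxcl12 (0.86), Tnfrsf11b (0.73), Lpl (0.67), Egr3 (0.65), Sp7 (0.63) and Il7 (0.61). Itga11 (-0.50), Jun (-0.62), Hyou1 (-0.68, detected on no array at 64 h, so at least 1.22-fold lower), Timp1 (-0.73), Prl2c2 (-0.96) and Aldh3a1 (-0.97) fell. Tmem184a (-1.01), Trem2 (-1.06), Adssl1 (-1.08), Prl2c3 (-1.12), Col18a1 (-1.17), Aqp1 (-1.22), Timp3 (-1.33) and Klk8 (-1.42) fell further. Several of these calls are weak. Of 25 alternatives, Itga11 lost its call in 16 (adjusted p up to 0.157), Hyou1 in 15 (0.151), Tnfrsf11b in 8 (0.153), Il7 in 7 (0.129), Sp7 in 7 (0.115), and Lpl (0.129), Egr3 (0.0969) and Jun (0.137) in 5 each. Itga11 lost it without any 1 of the 12 arrays. A second probe of Egr3 had the opposite sign. With the pair of arrays that stood apart left out, Rspo2 (0.121), Thbs1 (0.0844), Rasl11a (0.0828), Itga1 (0.0623), Lyz2 (0.059) and Rbp4 (0.0529) did not pass. The log2 changes of Rspo2, Rasl11a, Itga1, Lyz2 and Rbp4 were then 0.98 to 1.16, with fewer arrays per group.

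DNA replication and G2/M genes were lower than vehicle at 32 h (medians -0.37 and -0.42) and 64 h (-0.33 and -0.35), and at 96 h both lists were higher than at 32 h (adjusted p = 3.34e-07 and 6.96e-10) and 64 h (3.35e-09 and 5.14e-11). A difference in brightness between array labels is argued against: 0% of 10000 random lists matched on mean intensity had a median as low in any of the 4 cases. Under 6 other settings of the processing, 24 of 24 tests were lower (largest adjusted p = 9.32e-05, with a preset correlation). The deposited values differ from those used here by at most 0.0193 log2, so they repeat the main result. The higher offset and the 6 arrays compared alone keep the same background correction and quantile step. The processing is argued against by the settings without background correction, with median scaling and with each array label normalized on its own. With an estimated correlation the G2/M list at 64 h did not pass (adjusted p = 0.0664). G2/M at 32 h (0.00505) and DNA replication at 32 h and 64 h (0.00156 and 0.0136) did. A batch of cultures, RNA or hybridisations shared by the 32 h and 64 h samples stays open, because vehicle and 96 h carry the other array label. From 32 h to 64 h, within array label 2, the camera test gave adjusted p = 0.611 for DNA replication and 0.221 for G2/M. Their medians, 0.0707 and 0.0958, lay at percentiles 95 and 97.5 of the matched random lists. Neither list passed the camera test, and array label and time cannot be told apart. A slower division at 32 h and 64 h that eases by 96 h, from the drug or from the culture, may be the biological explanation and was not tested.

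Prl2c2, Prl2c3 and Prl2c4 fell by a similar factor at each time against vehicle. The largest difference between the 3 genes was 1.43 standard errors of a difference, as 1 transcript read by the probes of all 3 paralogs would give. Regulation of the 3 genes together gives the same result and stays open, so these may be 1 change or 3.

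Adipoq, Lpl and Cd36 rose at 96 h, and a share of cells turned into mature adipocytes is a candidate explanation. Of Fabp4, Plin1, Cfd, Cidec, Lep and Retn, 5 have a probe, 0 were detected on all 3 arrays at 96 h, and the highest mean was 4.92 log2 for Lep, against a median of 4.55 over all probes. This excludes nothing, because only 1 of them passed the detection filter and the genes were picked with that known, so mature adipocytes and a change of these genes in stromal cells cannot be told apart.

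For each comparison there are 10 splits of its 6 arrays, too few for a share under 0.05, and 1 of them, the real one itself, called as many probes as the real one. Each split was fitted to its 6 arrays alone on the values normalized and filtered over all 12, so the counts differ from those of the 12-array fit and of the 6 arrays normalized and filtered on their own. Against vehicle the real split gave 2308 probes at 96 h, 509 at 32 h and 1900 at 64 h. From 32 h to 64 h it gave 98, and the highest other split gave 0 in each comparison. Each other split mixes arrays of both groups, so a real difference adds to its spread and makes low counts likely. The 0 therefore does not show how often chance would give such counts.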

How the results depend on the processing

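Array weights and leaving out a pair of arrays were chosen after the data had been seen; the other alternatives were planned. Under the alternatives, 0 calls of the named genes reversed: 2810 of 2987 values at 96 h against vehicle kept their call or lack of one, 2871 of 2994 from 32 h to 64 h, 2897 of 3058 at 32 h and 2923 of 3055 at 64 h. The 20 largest changes of each comparison kept their call in 500 of 500 fits each, except from 32 h to 64 h, where Itga1, Lyz2, Rasl11a, Rbp4 and Rspo2 lost it with the pair of arrays left out (495 of 500 kept). Where no value below explains a change, the cause was not tested.

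Without background correction, 245 and 218 probes rose and fell from 32 h to 64 h and 534 and 583 at 32 h, 3 lists fell at 96 h, and the overlaps of 114 and 336 genes became 270 and 550. With the 6 arrays compared alone, which leaves fewer samples, 60 and 59 probes changed from 32 h to 64 h and 69 genes overlapped. With no filter 3 lists fell at 96 h and 3 rose at 64 h against vehicle. The strict filter gave 149 and 143 probes and 2 rising lists from 32 h to 64 h and an overlap of 173. Offset 50 gave 207 and 193 from 32 h to 64 h, 521 and 569 at 32 h, 4 rising lists at 96 h, and overlaps of 233 and 509. Trended and robust variances gave 236 and 219, 558 and 548, and overlaps of 261 and 511. At least 1.5-fold left 799 and 808 at 96 h and 683 and 700 at 64 h, since it adds a threshold. An estimated correlation left 0 rising and 0 falling lists at 96 h and from 32 h to 64 h, 2 rising at 32 h, and 0 rising and 1 falling at 64 h. The mean of a gene's probes gave 5 rising and 2 falling lists at 96 h. Leaving out 32 h replicate 3 and 64 h replicate 3 gave 20 and 23 probes from 32 h to 64 h, 214 and 203 at 32 h, and overlaps of 29 and 213. Each array label normalized on its own gave 289 rising and 494 falling probes at 32 h (345 and 357 otherwise) and 889 and 1414 at 64 h (1077 and 1128 otherwise).

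With each array left out in turn, 909 to 1230 probes rose and 982 to 1289 fell at 96 h, 49 to 88 and 51 to 80 from 32 h to 64 h, 209 to 336 and 188 to 357 at 32 h, and 753 to 1085 and 792 to 1138 at 64 h. Rising and falling lists ranged from 2 to 3 and 1 to 2 at 96 h, 0 to 1 and 0 to 1 from 32 h to 64 h, 4 to 5 and 3 to 5 at 32 h, and 3 to 5 and 3 to 5 at 64 h; the overlaps ranged from 68 to 102 and 216 to 329. Each array but 96 h replicate 2 moved at least 1 count by over 1.5 times. For probes and overlaps the counts are given beside each comparison. Falling lists at 96 h became 2, from 1, without 96 h replicate 3, and rising lists at 64 h became 3, from 5, without vehicle replicate 3 or 96 h replicate 1. Both lists from 32 h to 64 h were lost without 32 h replicate 2 or 64 h replicate 2. Over all 27 alternatives of the list tests at 64 h against vehicle, the adipocyte call was lost in 9 and the Notch call in 11.

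The replicate number as a block ended the Notch pathway call at 64 h (adjusted p = 0.0535) and left the counts of probes within 1.5 times. Pairing by number was weak at most: over 18 pairs of arrays with the same number in different groups the residuals correlated at r = -0.0218 to 0.0549. The median was 0.006, against -0.00469 for pairs with other numbers. Of 12 arrays, 7 correlated best with their own number, more than random matches would give on average, so weak pairing is not excluded. Signal over background limits the genes seen: 18897 of 45281 probes passed the filter. The median change over all probes was at most -0.0469 log2 from 0 under any scaling.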

Other observations

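The genes in this part were chosen after their values were seen, and no test was added for them beyond limma's, which all passed at 96 h against vehicle. Genes that rose included the Wnt activator Rspo3 (2.00 ± 0.17 log2), angiotensinogen, Agt (2.05 ± 0.27), haptoglobin, Hp (2.42 ± 0.13), the receptor ligand gene Gas6 (1.55 ± 0.12), Esm1 (1.92 ± 0.16), Bmper (1.47 ± 0.16), Smoc1 (1.45 ± 0.12), Nid2 (1.89 ± 0.11) and Mfap5 (2.03 ± 0.14). Npr3, a clearance receptor for natriuretic peptides, rose 5.42-fold (2.44 ± 0.14). Others that rose were the glycerol channel gene Aqp7 (1.64 ± 0.17), Car3 (1.47 ± 0.22), Mest (1.68 ± 0.12) and the dehydrogenase genes Adh1 (1.83 ± 0.16) and Aldh1a7 (2.06 ± 0.13). The transcription factor gene Runx1 (1.67 ± 0.14), the kinase gene Sphk1 (1.84 ± 0.13) and the Wnt receptor gene Fzd5 (1.44 ± 0.14) also rose.

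Genes that fell at 96 h included Ly6c1 (-2.35 ± 0.23), Cdh13 (-1.91 ± 0.14), podoplanin, Pdpn (-1.51 ± 0.13), and the innate receptor gene Tlr2 (-1.47 ± 0.20). So did Sparcl1 (-2.18 ± 0.16), Ltbp1 (-1.82 ± 0.18), the plasminogen activator gene Plat (-1.54 ± 0.18), pleiotrophin, Ptn (-1.54 ± 0.20), and the anchoring fibril collagen gene Col7a1 (-1.75 ± 0.16). The transcription factor gene Zic4 (-2.25 ± 0.15), the actin-capping gene Capg (-2.00 ± 0.13), the galectin gene Lgals3 (-1.46 ± 0.10), and the glycolysis genes Pfkfb4 (-1.79 ± 0.13) and Eno3 (-1.46 ± 0.13) fell as well.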
